A study of Drosophila melanogaster with 2 samples.

How the data were processed

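Chromatin immunoprecipitation sequencing was carried out by the authors on 2 biological replicates of whole Drosophila melanogaster embryos aged 0 to 24 h that expressed an Rfx-eGFP fusion. Per the labels, chromatin was sonicated to fragments of 200 to 800 bp and precipitated with an anti-GFP antibody, although the antibody field reads Rfx, and the build is dm6. The deposited files are peak lists. The authors called peaks against a control library and scored them with the irreproducible discovery rate (IDR). It is low for peaks that rank consistently high in the compared sets. The aligner, the peak caller and their versions are not given in the sources used here. The control library was not analysed here.

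Each deposited peak has a start, an end, a summit and a signal, the caller's enrichment value on a scale the sources used here do not state, so that signals were compared within a list only. The deposited score is the IDR on a whole-number scale up to 1000; the lowest score in each thresholded set is 830, which corresponds to an IDR of 0.01. In the ranked lists the authors also give the IDR as minus log10 (-log10 p scale), a deposited column that was not used in any test. A further 16 columns, counted over both series-level ranked lists together, hold the values of the compared inputs and were not used here. The thresholded sets list 1 additional input of unstated kind that the ranked lists do not. The files hold no read counts, so the depth of each replicate is unknown; Wilson intervals are over peaks or genes and cover counting error only.

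The main set was the larger series-level thresholded set. Peaks on the arms 2L, 2R, 3L, 3R, 4, X and Y were kept, which left out 3 peaks. The genome sequence was the reference of the same build and the annotation was Ensembl release 115 (BDGP 6.54). Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with seed 20 and a threshold of 0.05 on two-sided p. Adjusted p values are Benjamini-Hochberg values over the arms, the 10 motifs or the 20 lists, and for strength or matched genes over the lists tested. Both replicates formed 1 group, no samples were left out, and no condition was contrasted.

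An overlap of at least 1 bp counted as shared between replicates, against 100 shuffles of the intervals on the same arm; unshared peaks were shuffled in the same way against the other ranked list. For rank agreement, each main-set peak took the highest signal among the peaks of a replicate's ranked list that hold its summit. The same signals gave the percentile of each named peak in each replicate, reported as mean and SD over the replicates. Summits were assigned in order to within 500 bp of a TSS, exon, intron or intergenic DNA and compared with 1000 random placements on the same arm. Peaks per arm were tested with exact binomial tests against arm length. Motifs were matched without mismatch on either strand within 100 bp of the summit. By exact McNemar tests they were compared with the window 1000 bp downstream on the plus strand, whatever the strand of the gene. The strict X-box was GTNRCC, a spacer of 0 to 3 bases, and RGNAAC; the degenerate one was RYYNYY, a spacer of 1 to 3, and RRNRAC. X-box sequences are printed as on the plus strand. The shares of the strict X-box in the strongest and weakest of 5 equal parts were compared by Fisher's exact test.

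Lists of genes were tested by Fisher's exact test for a summit within 500 bp of a TSS, against all other protein-coding genes. Peak strength was tested by permutation with 100000 draws in lists with at least 3 genes with a peak. The 5 cilium lists were intraflagellar transport, BBSome and ciliary GTPases, transition zone and basal body, axonemal dynein and its assembly, and mechanosensory channel and dendrite. The others were sensory neuron determination, neurons, glia, muscle, hemocytes, segmentation and Hox, testis, centriole, DNA replication and cell cycle, cytosolic ribosomal proteins, respiratory chain, heat shock proteins, odorant and gustatory receptors, Jonah and trypsin digestive proteases, and tRNA genes. Names that matched no current symbol or single synonym were left out, namely 4 of 24 transport, 1 of 9 BBSome, 6 of 18 transition zone, 4 of 19 dynein, 1 of 9 mechanosensory, 1 of 15 sensory and 1 of 19 testis names.

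The groups, main tests, lists, motifs, the rule for named genes and the first set of alternatives were chosen before the data were examined. The rule named the 12 protein-coding genes with the strongest TSS peak that the conservative set also held; of each cilium list up to 5 genes with the strongest peak and up to 3 without one, in alphabetical order; the 8 strongest peaks with a strict X-box; Rfx; and up to 3 genes with the strongest peak of each other list past the threshold. Alternatives were the conservative set, each replicate alone, a stricter IDR, TSS windows of 250 and 1000 bp, protein-coding genes only, motif windows of 50 and 150 bp, other control windows, the degenerate X-box, 10 parts by strength in place of 5, other definitions of overlap, nearest TSS only, and 10000 draws of genes matched on length and distance to the next TSS. Added after seeing the data were top-score peaks only, the 4624 strongest peaks, removal of peaks with a signal under 20, the full palindrome, its single arm, and the comparison of X-boxes in the peaks of cilium genes.

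The code was tested on simulated data. With X-boxes planted at 450 of 9000 summits, summit windows with the site exceeded control windows by 448. With none planted the excess was 1. A planted share of 56.7% of summits near a TSS was returned as 56.2%, an overlap of 60% as 61.4%, and a list planted at 80% as 83.5%. In that simulation 1 of 18 unchanged lists was called, and over 100 simulations with no list changed the most calls for any list were 3, for odorant and gustatory receptors.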

Results

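The data were chromatin immunoprecipitation sequencing of Rfx, the fly member of the RFX family of transcription factors, which are known regulators of genes for building cilia and bind a palindromic site called the X-box. Transgenic Drosophila melanogaster carried an Rfx-eGFP fusion, and DNA from whole embryos aged 0 to 24 h was recovered with an anti-GFP antibody. The series held 1 group of 2 biological replicates, so it posed the question of where Rfx-eGFP was found in embryos and how far the replicates matched, not a contrast of conditions. The files gave peaks on the dm6 build and no read counts, so the sequencing depth of each replicate is unknown, and the authors' control library was not analysed here. The main set, called from both replicates, held 9250 peaks, of which 9247 lay on the 7 chromosome arms. They had a median width of 344 bp, covered 2.76 Mb or 2.00% of the arms, and ranged in signal up to 6098.94 with a median of 119.6. The replicates' own sets held 6297 and 6953 peaks, and a conservative set from both held 6978.

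Most peaks of one replicate were found in the other, and unshared peaks were weaker. Of 6290 replicate 1 peaks on the arms, 72.6% overlapped a replicate 2 peak (95% Wilson interval 71.5 to 73.7), against 2.91% ± 0.208 (SD over 100 shuffles) after random placement. Of 6953 replicate 2 peaks, 66.6% overlapped a replicate 1 peak (65.5 to 67.7), against 2.62% after random placement. Peaks without a partner were weaker, with a median signal of 59.9 against 125.35 for shared peaks in replicate 1 and 55.1 against 91.0 in replicate 2. Of the unshared peaks, 89.5% of those from replicate 1 and 69.7% of those from replicate 2 overlapped a peak in the other replicate's longer ranked list, against 33.9% ± 1.13 and 31.9% ± 0.979 (SD over 100 shuffles) after random placement. The shuffles ignored the starts of genes, although 50.4% of main-set summits lay within 500 bp of one. The excess over shuffles thus does not separate matching peaks from a common preference for promoters. Across the 8217 main-set peaks with a signal in both ranked lists, the Spearman correlation of the signals was 0.693, and peaks are not independent replicates. These peaks were selected by IDR and by their presence in both lists, which favours agreement, so the value does not describe all ranked peaks.

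**Figure D1:**
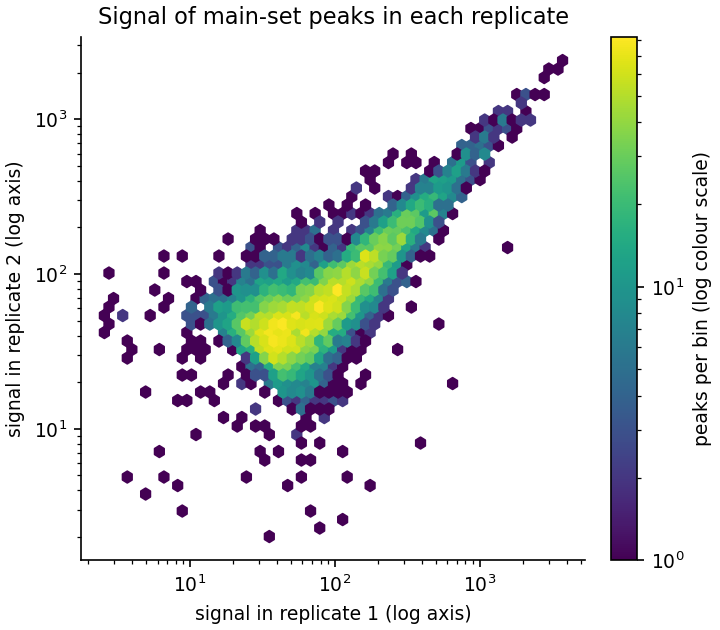
Signal of each main-set peak in the ranked list of replicate 1 (x axis) and of replicate 2 (y axis), both on log axes and in the caller's units, with colour giving the number of peaks per bin on a log scale. Signals rise together, with a Spearman correlation of 0.693 over 8217 peaks.

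Rfx-eGFP peaks were concentrated at the starts of genes. Of the 9247 summits, 50.4% lay within 500 bp of a transcription start site (TSS) (Wilson interval 49.4 to 51.4), 3.71 times the 13.6% of random placements. Introns held 33.3% of summits against 39.5% at random, intergenic DNA held 11.97% against 27.2%, and exons held 4.29% against 19.7%. The share near a TSS was 54.2% ± 1.91 (SD, n = 2) in the replicates' own sets, a spread far smaller than the distance to the random share. Each of the 4 location classes gave a two-sided p of 0.002, the smallest that 1000 placements can give.

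**Figure D2:**
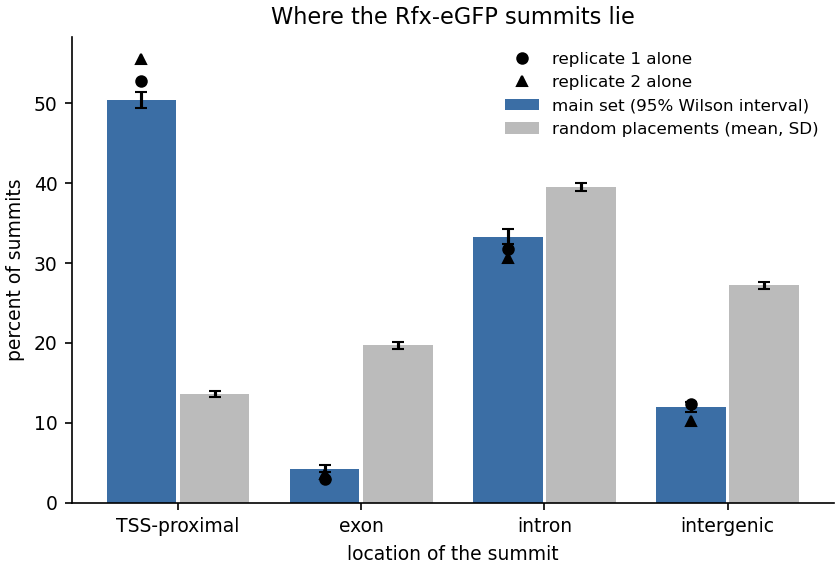
Percent of summits in each location class for the main set (blue bars, 95% Wilson interval) and for random placements on the same arm (grey bars, mean and SD over 1000 placements), with each replicate's own set as a black symbol. The TSS-proximal class holds 50.4% of main-set summits and 13.6% of random ones.

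The strongest promoter peaks lay at genes outside the cilium lists, as did most promoter peaks. The 12 protein-coding genes with the strongest TSS peak were Ugalt, CG14100, mRpL41, Tcs5, eIF6, CG7601, PNPase, CenG1A, CG5611, Shc, Art3 and mRpL23, with signals from 2866 to 6098.94. Ugalt (FBgn0024994), a UDP-galactose transporter, had the highest signal of the set, 6098.94, in a peak on X from 2703688 to 2704074 with its summit at -40 bp from the TSS. CG14100 (FBgn0036889) followed with 5796 on 3L from 19590433 to 19590806. The mitochondrial ribosomal protein genes mRpL41 (FBgn0034001; 2R, 15217570 to 15217998) and mRpL23 (FBgn0035335; 3L, 2373438 to 2373789) had signals of 4668 and 2866. PNPase (FBgn0039846), a mitochondrial RNA-processing enzyme, had 3486, and eIF6 (FBgn0034915), a factor of ribosome assembly and translation, had 3965 at a summit inside an antisense RNA, asRNA:CR45928. Within each replicate these peaks stood between percentile 99.8 ± 0.0907 (SD, n = 2; mRpL23) and percentile 100 ± 0 (Ugalt) of the main-set signals. None of the 12 had a strict X-box within 100 bp of its summit. Only 27 of the 4949 protein-coding genes with a TSS peak were in the cilium lists, and 0.757% of all summits had a strict X-box. With 12 genes, neither absence sets these peaks apart from the rest.

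Peak density was similar on the large arms, somewhat higher on X, and very low on chromosomes 4 and Y. The X chromosome held 73.8 peaks per Mb and the 4 arms of chromosomes 2 and 3 between 66.1 and 70.5, against 67.2 over all arms. Chromosome 4 held 4 peaks, 2.97 per Mb (adjusted exact p = 5.81e-33), and Y held 1 peak, 0.273 per Mb (adjusted exact p = 9.31e-106). Chromosome 4 held 1.48 per Mb in replicate 1 alone and 12.6 in replicate 2 alone, against 45.7 and 50.5 over all arms together (adjusted exact p = 1.94e-23 and 7.77e-13). Of 80 protein-coding genes on chromosome 4, 3 had a peak at a TSS, or 3.75% (Wilson interval 1.28 to 10.5) against 35.6% of the other genes (exact p = 1.12e-11). The excess on X passed the test in the main set (adjusted exact p = 5.24e-05) and in replicate 1 alone (55.0 per Mb, adjusted exact p = 1.74e-12) but not in replicate 2 alone (51.0 per Mb, adjusted exact p = 0.750), where 2L and 2R passed instead (53.8 and 54.9 per Mb, adjusted exact p = 0.0271 and 0.00163). 2L also passed in the conservative set (adjusted exact p = 0.0474) and in the 4624 strongest peaks (0.0109), and not in the main set (0.0927). The reference rate was taken over all arms, and the few peaks on 4 and Y lower it. The calls on X, 2L and 2R are not separated from that effect. Summits are also not independent, so these p values describe only the placement of these peaks.

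The X-box was found at few Rfx-eGFP summits, slightly more often than in neighbouring DNA. A strict X-box lay within 100 bp of 70 of 9247 summits, 0.757% (Wilson interval 0.600 to 0.955), against 43 of the same windows placed 1000 bp downstream on the plus strand, 0.465% (0.345 to 0.626), a ratio of 1.63 (exact McNemar p = 0.0132). In windows of 100 bp, the share was 0.433% at the summit and 0.184% and 0.151% in the windows next to it. The more specific full palindrome, GTTGCC, spacer, GGCAAC, was found at 11 summits and 2 control windows (exact p = 0.0225), and a single arm, GGCAAC, at 13.2% of summits and 10.2% of control windows (exact p = 1.68e-10); both were chosen after seeing the data. A degenerate X-box was found at 19.2% of summits and 19.6% of control windows (exact p = 0.477). The share of summits with the strict site did not rise with peak strength past the threshold, with 0.757%, 0.703%, 0.757%, 0.973% and 0.595% in 5 equal parts from the strongest to the weakest peaks (first against last, exact p = 0.689). Against control windows, the 4624 strongest peaks had 0.670% against 0.303% (ratio 2.21, exact p = 0.0161). The call did not hold in replicate 1 alone (0.509% against 0.429%, exact p = 0.597) or in the conservative set (exact p = 0.195), whereas replicate 2 alone gave 0.849% against 0.475% (exact p = 0.00878); over all alternatives for the strict site p ranged from 0.00206 to 0.597.

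**Figure D3:**
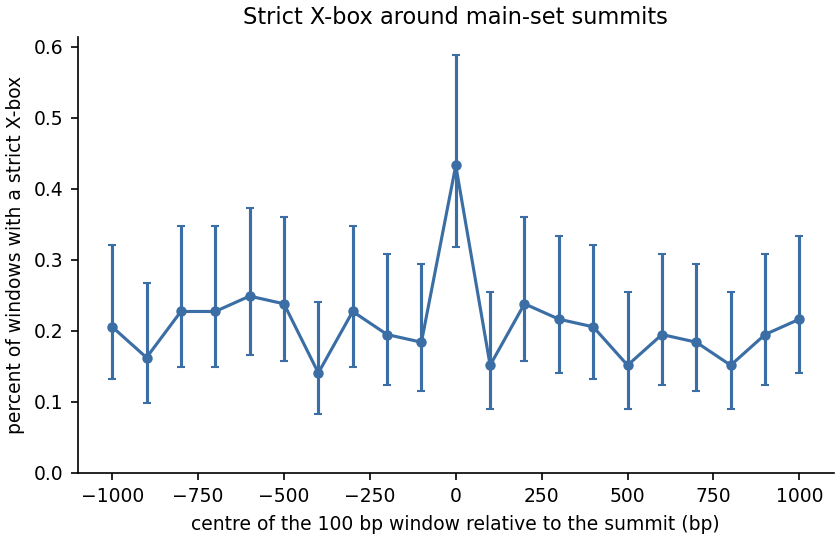
Percent of windows of 100 bp with a strict X-box (y axis) by the position of the window's centre relative to the main-set summit in bp (x axis), with 95% Wilson intervals over 9247 summits. The window at the summit holds 0.433%, and the windows on either side of it hold 0.184% and 0.151%.

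The strongest peaks with an X-box included 2 at cilium genes, IFT52 and Fam92, and 1 inside the cilium gene dnd. The peak at lncRNA:CR31044 (FBgn0051044; 3R, 29214273 to 29214612) had a signal of 1980 and the site GTAACCAAGCAAC, and that at sgll (FBgn0051472; 3R, 7810136 to 7810504) had 1092 and GTTTCTGGGCGAC. A peak in an intron of dnd, with its summit -15 bp from the TSS of CG6678 (FBgn0038917; 3R, 21886883 to 21887165), had 825 and GTTTCCATGGCGAC. The others were CG31855 (657, GTCACCACCAGTAAC), lncRNA:CR44800 at a distance of 4871 bp (645, GTTTCCGGTGAC), fkh, which encodes a forkhead transcription factor (618, GTTGCCAGGCAAC), IFT52 (569, GTTGCCCGGCAAC) and Fam92 (429, GTTGCCTTGGTAAC). Their percentiles in the replicates lay between 88.8 ± 9.12 (SD, n = 2; Fam92) and 99.5 ± 0.268 (lncRNA:CR31044). Of the 70 summits with an X-box, 40 were TSS-proximal.

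The DREF, Motif 1 and CTCF sites stood further above their control windows than the strict X-box did. The full palindrome X-box had a ratio of 5.5, above that of CTCF, on 11 summits and 2 control windows. Only the strict X-box was also compared with random windows at the same TSS distance (ratio 1.84, Fisher's exact p = 0.00261). Those windows lay away from all summits, so this test does not separate binding from the sequence of promoters that have a peak. For the other motifs, with 50.4% of summits TSS-proximal, the excess is not separated from the sequence of promoters in general. The DREF site, a core promoter element of housekeeping genes, was found at 4.82% of summits and 0.497% of control windows (ratio 9.70, adjusted exact p = 8.28e-83). The Motif 1 site, another core promoter element, was found at 2.45% against 0.346% (ratio 7.09, adjusted exact p = 1.33e-37), and the core site of the insulator protein CTCF at 0.854% against 0.195% (ratio 4.39, adjusted exact p = 6.80e-10). The short site of the insulator protein BEAF-32 was found at 31.0% against 21.4% (adjusted exact p = 1.59e-48). In the replicates' own sets the ratio was 10.9 ± 1.79 (SD, n = 2) for DREF, 9.14 ± 0.404 for Motif 1, 5.21 ± 0.901 for CTCF and 1.55 ± 0.0157 for BEAF-32. GAGA repeats were more frequent at main-set summits (4.82% against 3.43%, adjusted exact p = 4.02e-06) and in replicate 2 alone (5.93% against 3.52%, adjusted exact p = 6.97e-11). The excess was absent in replicate 1 alone, where the share was lower at summits but not past the threshold (3.18% against 3.78%, adjusted exact p = 0.104). The E-box (11.0% against 9.90%) and the site of the early activator Zelda (1.04% against 1.44%, lower at summits) each had an adjusted exact p of 0.0185, and neither call held in the conservative set (adjusted exact p = 0.185 and 0.0606) or in replicate 1 alone (0.859 and 0.0740). In replicate 2 alone the E-box passed (0.000104) and Zelda did not (0.0562), and neither passed in the 4624 strongest peaks (0.794 and 0.358). The TATA box did not differ past the threshold (1.80% against 1.49%, adjusted exact p = 0.131). The panel held 10 motifs, the X-boxes included.

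The 5 lists of cilium genes, fixed as the genes Rfx would be looked for at, had peaks at 27 of 63 members, and none of the 5 passed the test against the 35.4% of all 13968 protein-coding genes with a TSS peak. The lists were small, so a difference is not excluded. Wilson intervals were 34.2 to 74.2 for transport, 21.5 to 78.5 for BBSome and 25.4 to 74.6 for transition zone genes. They were 15.2 to 58.3 for dynein and 2.24 to 47.1 for mechanosensory genes. Intraflagellar transport genes, which move cargo along the cilium, had a peak at 11 of 20 (55%, adjusted exact p = 0.229), the strongest at Oseg5 (FBgn0032891; 2L, 20835579 to 20835843; signal 743), IFT52 (FBgn0031829; 2L, 6557411 to 6557648; 569) and IFT43 (FBgn0032446; 2L, 12694898 to 12695091; 385), then at Oseg6 (219) and Kap3 (177). The dynein gene btv, Cluap1 and IFT20 were among the members without a peak. The BBSome and ciliary GTPase genes had 4 of 8 (50%, adjusted exact p = 0.517), at dnd (825), CG11356 (87.6), BBS4 (63.6) and BBS1 (52.4), while Arl6, BBS5 and BBS8 had none. Transition zone and basal body genes had 6 of 12 (50%, adjusted exact p = 0.516), including Fam92 (429), unc (202), Mks1 (138), Cc2d2a (106) and Cep290 (92.0), while B9d1, B9d2 and Cep164 had none. Axonemal dynein and assembly genes, which make cilia beat, had 5 of 15 (33.3%, adjusted exact p = 1), at tilB (154), Ccdc114 (126), Dhc36C (124), Dnah3 (107) and Dnaaf5 (87.5), while the dynein heavy chain genes Dhc16F, Dhc62B and Dhc93AB had none. Of 8 mechanosensory genes, only the channel gene nompC (92.7) had a peak (12.5%, adjusted exact p = 0.456), and DCX-EMAP, eys and iav had none.

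Several of these peaks differed between replicates or lay closer to another gene. IFT52 stood at percentile 93.9 ± 2.07 (SD, n = 2) of the replicates' signals, Kap3 at 63.8 ± 4.196 and Dhc36C at 48.9 ± 0.830, whereas Cc2d2a stood at 35.1 ± 43.0, Cep290 at 30.5 ± 37.9 and Mks1 at 42.2 ± 38.6. Dnah3 had no replicate 2 value. The TSS nearest to the summit was that of msl-3 for BBS1, CG15445 for unc, mdu for Mks1, CG14615 for tilB, mEFTs for Dhc36C and CG6678 for dnd. The IFT52 peak was also within 500 bp of COX5B, a respiratory chain gene. The intraflagellar transport list passed the test in replicate 2 alone (60%, adjusted exact p = 0.0179) and when each peak went to its nearest TSS only (55%, adjusted exact p = 0.0319), with a range of 0.0179 to 0.454 over all alternatives; replicate 1 alone gave 40%. Of the other lists, 3 had lower shares in each replicate's own set: 12.5% and 37.5% for BBSome, 25% and 41.7% for transition zone and 13.3% and 26.7% for dynein genes, in replicates 1 and 2. The share of other genes also fell, from 35.4% to 28.2% and 29.6%, in these smaller sets. In the main set no cilium list passed the test on the strength of its peaks. Mean percentiles among all genes with a peak were 51.9, 28.2, 40.7 and 31.5 for transport, BBSome, transition zone and dynein genes (permutation, adjusted p = 0.936, 0.547, 0.875 and 0.547). They rested on 11, 4, 6 and 5 genes, too few to exclude a difference. Among the 4624 strongest peaks, 3 dynein genes had weak peaks for that set (mean percentile 7.84, permutation, adjusted p = 0.0218, range 0.0218 to 0.946 over all alternatives).

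Where a cilium gene had a peak, an X-box was there far more often than at other genes. Of the 27 cilium genes with a peak, 6 had an X-box at it, 22.2% (Wilson interval 10.6 to 40.8), against 44 of 4922 other genes, 0.894% (0.667 to 1.20; odds ratio 31.7, exact p = 1.97e-07). The 6 were IFT52, IFT43, dnd, Fam92, Cc2d2a and Dnah3. This comparison was chosen after seeing the data, and it does not separate binding from the sequence of these promoters: of 16 cilium genes with an X-box within 200 bp of a TSS, 8 had a peak (50%), against 19 of 47 without one (40.4%, exact p = 0.566).

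Among the 20 lists, cytosolic ribosomal protein genes and replication and cell cycle genes carried peaks most often, and digestive protease and receptor genes least. Cytosolic ribosomal protein genes had a TSS peak at 73 of 85 (85.9%, Wilson interval 76.9 to 91.7, adjusted exact p = 1.45e-20), and at 82.9% ± 2.50 (SD, n = 2) in the replicates' own sets. Their peaks were also strong, with a mean percentile of 70.5 (permutation p = 2e-05, the smallest the draws can give, adjusted p = 0.00028), led by RpL7 (1564), RpS27 (1496) and RpL23A (1118). DNA replication and cell cycle genes had a peak at 16 of 21 (76.2%, adjusted exact p = 0.00107), led by the E2F partner gene Dp (791) and the replication helicase genes Mcm2 (445) and dpa (403). Odorant and gustatory receptor genes had a peak at 5 of 119 (4.202%, adjusted exact p = 2.44e-15; 2.52% and 1.68% in replicates 1 and 2 alone): Gr63a (148), Gr97a (96.7), Gr21a (79.5), and Or10a and Gr10a, which share 1 peak (103). The Gr63a summit was nearest the TSS of Lamtor4, and Gr97a and Gr21a were named after their values were seen. Jonah and trypsin digestive protease genes had none of 25 (up to 13.3% by the Wilson interval, adjusted exact p = 0.000121), and testis genes had 1 of 18, bgcn (567; 5.56%, adjusted exact p = 0.0192). The tRNA genes had 52 of 290 (17.9%, adjusted exact p = 6.28e-10; 5.52% and 14.8% in replicates 1 and 2 alone and 9.31% in the conservative set), led by tRNA:Tyr-GTA-1-8 (826), tRNA:Phe-GAA-1-2 (621), whose summit was nearest RpL17, and tRNA:Val-CAC-2-5 (419), whose summit was nearest Naam. They were compared with protein-coding genes, for which a summit near any annotated TSS counted. The shares are thus unlike measures, and the lower share does not show that peaks avoid tRNA genes. Against genes of like length and spacing, the ribosomal and the receptor lists passed (adjusted p = 0.0019 each), replication genes (0.0551) and digestive genes (0.0555) did not, and testis genes (0.424) did not, here or in both replicates' own sets (adjusted exact p = 0.0974 and 0.0859); this test did not cover tRNA genes.

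**Figure D4:**
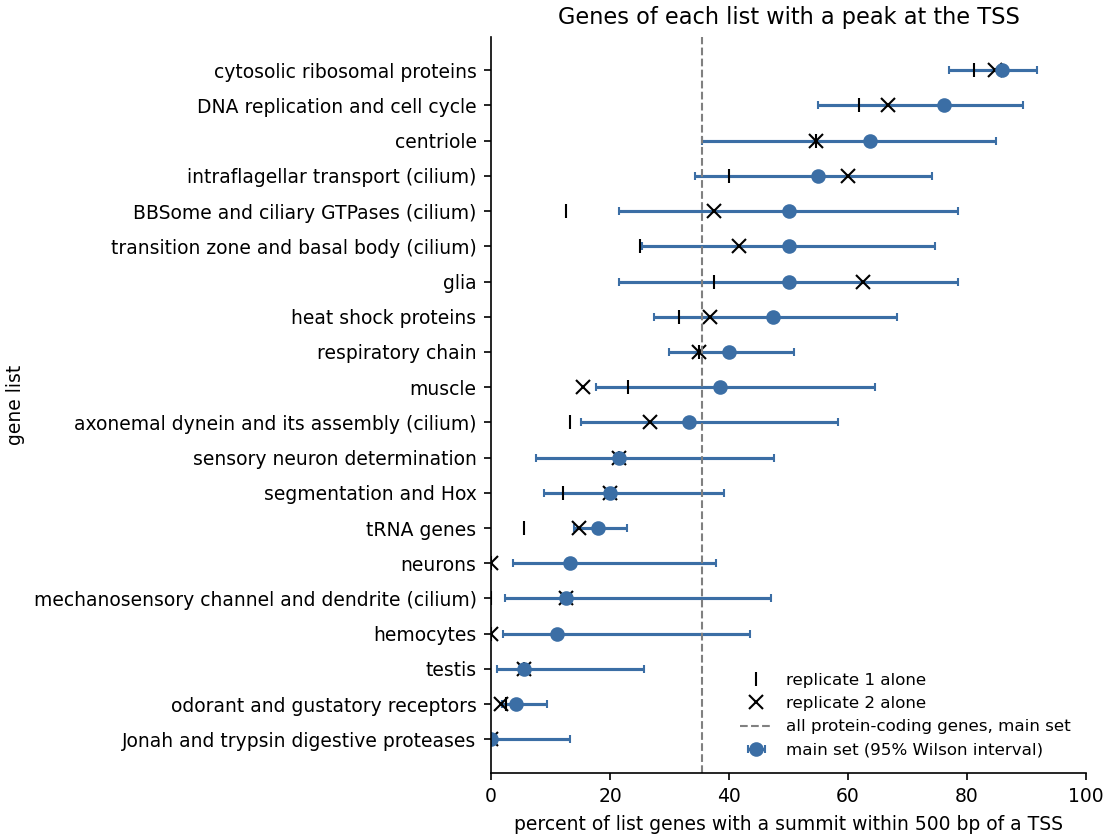
Percent of each list's genes with a summit within 500 bp of a TSS (x axis) for the main set (blue points, 95% Wilson interval) and for each replicate's own set (black marks), with the dashed line at 35.4%, the share of all protein-coding genes in the main set. Ribosomal protein genes stand at 85.9%, and odorant and gustatory receptor genes at 4.202%.

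The remaining 9 lists did not pass the test in the main set, and the neuron list passed in several other peak sets. Peaks were found at 2 of 15 neuron genes, cpx (62.5) and fne (73.1), at 3 of 14 sensory determination genes, elav (1418), N (194) and neur (189), and at 4 of 8 glia genes, of which moody had a signal of 2448. They were also found at 5 of 13 muscle genes, at 1 of 9 hemocyte genes (srp, 65.1), at 5 of 25 segmentation and Hox genes, at 7 of 11 centriole genes, at 32 of 80 respiratory chain genes and at 9 of 19 heat shock genes, of which Hsp27 had 1621. The adjusted exact p of these lists ranged from 0.176 (centriole) to 0.821 (muscle). In the sets of replicates 1 and 2 alone, muscle genes stood at 23.1% and 15.4% and glia genes at 37.5% and 62.5%. No hemocyte gene had a peak there. No gene of the neuron list had a peak in either replicate's own set (adjusted exact p = 0.0304 and 0.0240), in the conservative set (0.0279) or among top-score peaks (0.0137), with a range of 0.0137 to 0.637 over all alternatives. The genes and signals in these sentences were chosen after their values were seen.

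The Rfx gene itself carried peaks, and its promoter peak was absent from the main set. Rfx spans 3R from 10361760 to 10378068, and the main set had a peak of signal 646 from 10368335 to 10368620 and one of 103 from 10365328 to 10365671, both in its introns and without an X-box. A peak 79 bp from a TSS of Rfx, from 10378037 to 10378251, had a signal of 544 and the top score of 1000 in the ranked list, which passes the authors' threshold, but it was missing from the thresholded set. The same was true in replicate 1 (signal 227) and in replicate 2 (302). Other peaks past the threshold on both sides of Rfx were missing from the main set too, such as those of signal 666 in an intron of jumu and 215 in the 5' UTR of cwo. Whether the peaks at this locus reflect binding of Rfx-eGFP to its own gene was not tested. In all, 221 of 9468 ranked peaks past the threshold (2.33%) were missing from the main set, 147 of them on 3R and 48 on 2L.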

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

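Top-score peaks, the 4624 strongest peaks, removal of peaks with a signal under 20, the full palindrome, its single arm and the X-box comparison in cilium genes were chosen after seeing the data; the other alternatives were not. The stricter IDR of 0.01 removed no peak and decides nothing, and it is left out of the counts here. Of the remaining values under an alternative, 144 that answer a comparison kept their direction and side of the threshold or their size, 15 moved, 1 reversed, 3 lost the call and 3 gained it. Among single motifs, arms and other lists, 320 did so, 2 reversed, 21 lost the call and 8 gained it. The location result held in all alternatives, between 42.7% and 61.3% near a TSS. The cause was not tested for the changes that follow. The X-box difference of 0.292 points was 0.172 in the conservative set (exact p = 0.195), 0.0795 to 0.374 with either replicate left out, 0.249 in windows of 150 bp (exact p = 0.0598) and -0.422 for the degenerate site (exact p = 0.477). The 8 motifs past the threshold, which count the nested DREF and BEAF-32 sites separately, became 4 in the conservative set, 4 to 7 with either replicate left out and 5 in the 4624 strongest peaks. The GAGA difference of 1.40 points was 2.40 without replicate 1. It changed sign to -0.604 without replicate 2 and -0.0649 in the 4624 strongest peaks, neither past the threshold (adjusted exact p = 0.104 and 0.914). The intraflagellar transport list passed without replicate 1 (60%; range 40 to 60 with either left out) and with nearest TSS only (55%). Lists past the threshold on strength rose from 1 to 2 in the 4624 strongest peaks, where 3 dynein genes had a mean percentile of 7.84 (permutation, adjusted p = 0.0218, range 0.0218 to 0.946), and to 2 with a TSS window of 1000 bp, where 3 neuron genes had a mean percentile of 4.31 (permutation, adjusted p = 0.0056; no other alternative had enough neuron genes to test). Against matched genes, which did not cover tRNA genes, 1 list stayed higher in place of 2 and 1 lower in place of 3. With reciprocal overlap of 50%, summits within 100 bp and equal numbers of ranked peaks, 59.4%, 69.0% and 70.8% of replicate 1 peaks and 53.7%, 62.4% and 70.2% of replicate 2 peaks were shared. The Spearman correlation of peak signal between replicates was 0.765 in the conservative set. The unknown depth limits what a missing peak shows.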

Other observations

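The tests of a mislabelled sample, of active promoters and of weak peaks were chosen only after the results they bear on were seen; the others were not. The design has 1 group, so no biological explanation was tested for any pattern.

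Chromosome 4 was thin in the ranked list as well, with 23 peaks or 17.1 per Mb against 734 to 863 per Mb on the large arms; whether its reads were filtered or scaled differently was not tested. Of the main-set peaks, 217 had a signal under 20, and all 217 had another summit within 400 bp, against 7.29% of the rest.

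The strict X-box lay at 0.757% of summits. The rest of each peak, outside the summit window, held the site 0.119% of the time against 0.173% in shifted windows. The difference was -0.0541 points (exact p = 0.442). Strict X-boxes elsewhere in the peak thus do not account for the low share at summits. Whether summits lie away from bound sites of another form was not tested. Recovery of active promoters whatever the factor cannot be told apart: 85.9% of ribosomal protein genes had a peak without an X-box, but none of their peaks had one, so the value only restates the list result. A mislabelled sample with no Rfx in the precipitate cannot be told apart: at the 4435 summits near the TSS of a protein-coding gene the site was 1.67 times as frequent as at the same distance from such genes without a peak (exact p = 0.00634), but genes with an X-box near the TSS did not have peaks more often past the threshold (38.5% against 35.4%, exact p = 0.363). At the 4584 summits far from any TSS the ratio was 1.11 (exact p = 0.788), and the demand for an excess at genes was added after the 1.67 was seen.

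Peaks past the authors' threshold were missing from the thresholded sets, the Rfx promoter peak among them. Removal of weak peaks is argued against by their median signal of 152.8, above the 119.5 of the kept peaks. Removal of whole regions may account for them: for 80.5% of the missing peaks the nearest other peak past the threshold was missing too, against a mean of 4.99% and a highest of 11.3% in 1000 shuffles. What defined such regions stays open, because the kind of the additional input is not stated.

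Of 16 cilium genes with an X-box within 200 bp of a TSS, 8 had no peak: BBS5, BBS9, Cluap1, Dhc62B, IFT57, Ttc30, btv and dtr. Removal past the threshold is argued against, since 0 of the 8 X-boxes (0%) lay within 100 bp of a missing peak. Summits present but under the IDR threshold cannot be told apart from chance: 50% of the 8 had a ranked summit within 100 bp against 1 of 8 shifted windows, and the exact p of 0.25 rests on too few sites to decide.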
